A study of Mus musculus with 35 samples.

How the data were processed

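Single mouse embryos of the F1 cross C57BL/6J x CBA/H were profiled by RNA sequencing at the late 2-cell stage. By the labels, zygotes were microinjected 24 h after hCG, the hormone that triggers ovulation, cultured in KSOM medium and collected at 48 h. The library method, Smart-seq+5', is an adaptation of Smart-seq2 that yields fragments from transcript 5' ends beside fragments from inside the transcript. It starts from polyA RNA and was read as paired reads of 150 bp per the labels. The 35 embryos fell into 4 groups taken from the treatment label: 9 controls with a scrambled antisense oligonucleotide, 7 SRF-LOF embryos with mRNA of a dominant negative SRF, 9 DUX-LOF embryos with an antisense oligonucleotide against DUX, and 10 double-LOF embryos with both. By these labels the SRF-LOF embryos received mRNA and no oligonucleotide, and no group received a control mRNA. Each embryo is 1 library, and the labels name no batch, litter or injection day, so p-values measure the spread between these embryos.

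The authors deposited 2 count files per embryo, 70 in all, 1 of internal fragments and 1 of 5' fragments, with the read class taken from the file headers. Reads were aligned with STAR 2.7.11a to GRCm38 per the submitters' processing notes. The counting tool, its treatment of reads that map to several places, its use of strand and the annotation release were not given in the sources used here. The deposited internal values are raw counts of whole numbers. The deposited 5' values, listed as estimated counts in the record of units, were whole numbers of the same form, so rounding changed none. Each file holds 54838 gene rows, 1395 repeat subfamily rows and 92 ERCC spike-in rows. Gene names and GRCm38 coordinates came from GENCODE M21, which named 54723 of the gene IDs and left 115 without a name. Genes with near-identical copies (the Zscan4, Obox and Dux clusters) and repeat subfamilies share reads, so values of their single members are uncertain. Overlapping and antisense genes cannot be told apart.

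Internal gene counts per embryo ranged from 220921 to 2039475, and 5' gene counts from 505157 to 2343900. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3) on internal counts. All 4 groups entered 1 fit, so that they share an estimate of the spread between embryos. Library sizes and TMM factors came from the gene rows, and low rows were removed with filterByExpr, which left 11940 genes and 628 repeat subfamilies (11749 and 626 in 5' reads). Adjusted p-values follow Benjamini and Hochberg, separately for genes and repeats, at a threshold of 0.05 with no fold threshold, and every adjusted p below is from this test unless another is named. Comparisons were each LOF group against control, double-LOF against DUX-LOF and against SRF-LOF, and the interaction, which is the difference between double-LOF and DUX-LOF minus that between SRF-LOF and control. Log2 fold changes are given ± their standard error, and counts scaled to library size (CPM) as mean ± SD. Intervals are at the 95% level. A gene with 0 counts in a group has a lower bound on its fold from 3 counts over that group, and a gene with 1 to 3 counts a ratio with its counting interval. Both cover counting error only.

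The groups, tests, comparisons, 20 gene lists, 6 repeat lists, the naming rule and most alternatives were chosen before the data were examined. The gene lists cover DUX-linked 2-cell genes, maternal oocyte transcripts, SRF targets of the actin cytoskeleton and among immediate early genes, Obox homeobox genes, preimplantation transcription factors, ribosome biogenesis, ribosomal proteins, proteasome, spliceosome, nuclear oxidative phosphorylation genes, mitochondrial mRNAs, cell cycle, p53 targets, stress response, heat shock, interferon and RNA sensing, and markers of cumulus cells, sperm and blood cells. Of 699 entries 697 were matched. The repeat lists cover MERVL, older ERVL and MaLR LTRs, LINE-1, IAP and other ERVK, SINE and satellite repeats, with 52 of 52 entries matched. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation: of 36 calls with the preset value, 0 held with the estimated one. Mean log2 CPM per embryo was compared by two-sided exact permutation tests, 85 in all, added after the data were seen. Named genes are Srf, Duxf3, MERVL-int and MT2_Mm, up to 8 largest rises and 8 largest falls with a mean of at least 10 CPM, up to 4 members per list and up to 5 repeats per direction. Predicted genes and pseudogenes were left out of the rises and falls.

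Alternatives were DESeq2 1.42.0, its size factors in edgeR, no count filter, scaling from gene and repeat rows together, scaling to the maternal list, only the groups compared, replicate number as a block, 5' reads, and libraries under 0.25 of the median total left out (1 library). Scaling to ERCC spike-ins, leaving out each library in turn, leaving out 3 doubted libraries and summing or separating the MT2 rows were added after the data were seen. The code was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For SRF-LOF against control (11559 genes run) it recovered 13 and 69 of them with 4 false calls, for DUX-LOF (11537 genes) 16 and 71 with 5, and for double-LOF (11527 genes) 17 and 77 with 5. For the interaction (11527 genes) it recovered 3 and 37 with 4 false calls. Each gene was drawn independently, and the changed genes had at least 10 CPM. Variation that genes share was left out, so these numbers test the code and do not give the rates in the real embryos. No library pair of a group agreed within sampling noise, and no library was left out.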

Results

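RNA was counted in 35 single late 2-cell mouse embryos: 9 controls injected with a scrambled antisense oligonucleotide, 7 injected with mRNA of a dominant negative SRF (SRF-LOF), 9 injected with an antisense oligonucleotide against DUX (DUX-LOF) and 10 injected with both (double-LOF). SRF, serum response factor, is a transcription factor known for actin and immediate early genes. DUX is a homeodomain factor that switches on 2-cell genes and MERVL, an endogenous retrovirus whose LTR is MT2_Mm. The series asks what SRF does for MERVL and for gene expression while the zygotic genome is activated. Internal reads gave a mean of 1217250 gene counts per control, 1236980 per SRF-LOF, 1108020 per DUX-LOF and 909730 per double-LOF embryo, and 12915 to 21863 genes were detected per embryo. Repeats took 13.9% to 39.97% of gene and repeat counts.

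Reads on Srf (ENSMUSG00000015605.6, chromosome 17, 46548329 to 46556175, minus strand, GRCm38) separated the embryos with and without injected SRF mRNA. Srf stood at 24.8 ± 10.7 CPM in controls (SD, n = 9) and 25.0 ± 10.9 in DUX-LOF (n = 9), against 343 ± 235 in SRF-LOF (n = 7) and 702 ± 505 in double-LOF embryos (n = 10). The lowest SRF-LOF embryo had 97.0 CPM and the highest control 41.2. The rise was 3.79 ± 0.42 on the log2 scale in SRF-LOF (adjusted p = 7.4e-07) and 4.82 ± 0.42 in double-LOF (adjusted p = 6.6e-10). These reads cannot be split into embryonic and injected Srf RNA. Reads on Duxf3, the Dux gene of the annotation (ENSMUSG00000075046.7, chromosome 10, 58229979 to 58232675, minus strand), were few: 9.02 ± 7.19 CPM in controls, 16.3 ± 12.6 in SRF-LOF, 16.1 ± 38.0 in DUX-LOF and 10.8 ± 10.9 in double-LOF embryos. Their log2 fold changes of 0.87 ± 0.83, 0.87 ± 0.78 and 0.32 ± 0.78 were within the spread between embryos. The library labelled DUX-LOF 10 held 151 of these counts (117 CPM) while no other DUX-LOF library was above 8.12 CPM. Without it the DUX-LOF mean was 3.50 ± 3.06 CPM (n = 8).

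**Figure D1:**
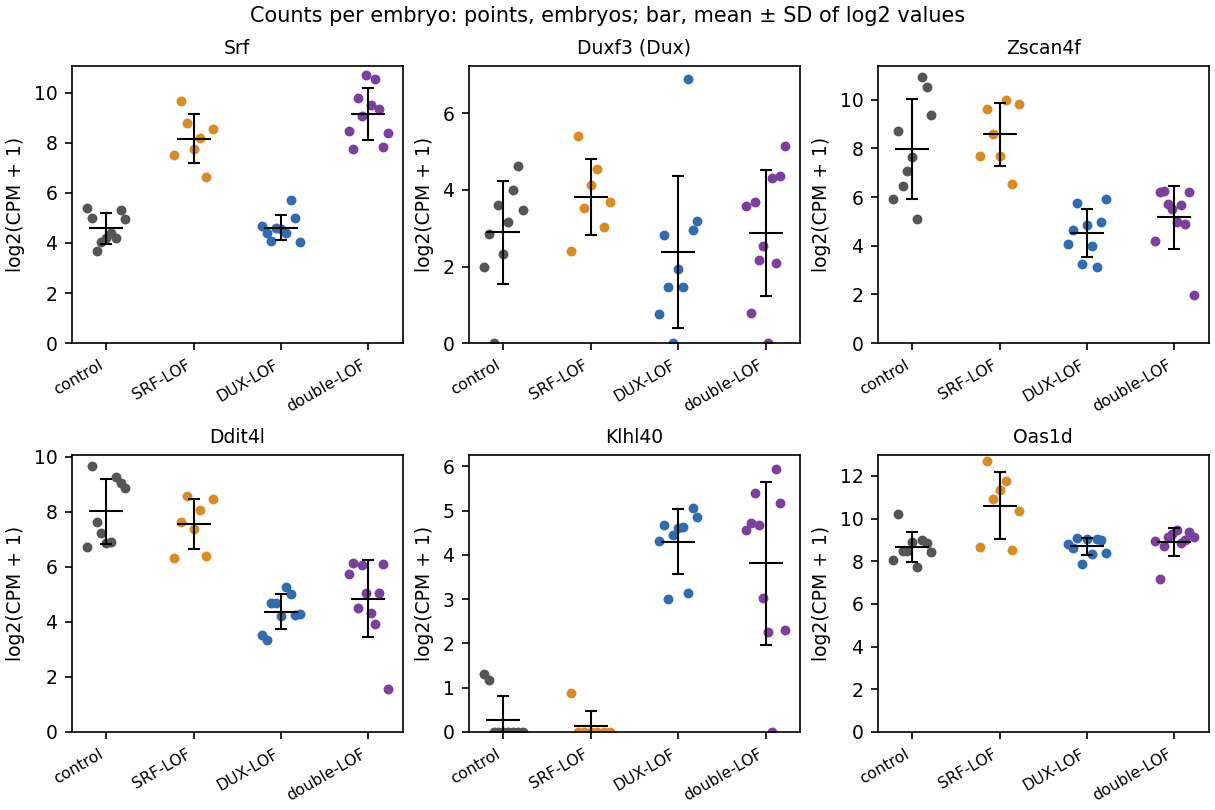
Internal reads of 6 genes per embryo, as log2(CPM + 1), by group, with 1 point per embryo and bars for the mean ± SD. Srf is higher in SRF-LOF and double-LOF, Zscan4f and Ddit4l lower and Klhl40 higher in DUX-LOF and double-LOF, and Oas1d higher in SRF-LOF; 1 DUX-LOF embryo stands apart in Duxf3 at 117 CPM.

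In SRF-LOF embryos the maternal gene Oas1d, an ovary-expressed member of the oligoadenylate synthetase family (ENSMUSG00000032623.9, chromosome 5, 120914536 to 120921652), rose by 2.37 ± 0.40 on the log2 scale, from 463 ± 289 to 2394 ± 2197 CPM (adjusted p = 0.0032, n = 7 against 9). In SRF-LOF 3 and 8 it stood at 404.8 and 364.1 CPM, within the control range of 210.1 to 1187 CPM. The other 5 embryos were above all controls. Akr1b3, an aldose reductase, rose by 2.22 ± 0.47 (adjusted p = 0.019), Dennd6a by 2.47 ± 0.50 (adjusted p = 0.016), and the oocyte and early embryo homeobox gene Obox2 by 1.91 ± 0.41 (adjusted p = 0.021). Hand1, a trophoblast and heart transcription factor, fell from 247 counts in controls to 1 in SRF-LOF, 180.6-fold with a counting interval of 32.1 to 7161.7 (adjusted p = 0.022), and Osbpl6, a lipid-binding protein gene, fell by 3.46 ± 0.78 (adjusted p = 0.022). MERVL-int stood at 11430 ± 4777 CPM in controls and 10510 ± 5399 in SRF-LOF embryos, a log2 fold change of -0.12 ± 0.35 (adjusted p = 0.97), and MT2_Mm at -0.07 ± 0.37 (adjusted p = 0.98). In 5' reads MT2_Mm was at -0.29 against control, also within the spread.

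Among 35 tested SRF targets of the actin cytoskeleton, 1 rose with SRF-LOF and 0 fell (1 and 0 adjusted over the list alone): Fermt2, a focal adhesion gene, at 1.24 ± 0.27 (adjusted p = 0.021). Among 15 SRF targets of the immediate early class 0 rose and 1 fell, Mcl1, an anti-apoptotic gene, at -1.62 ± 0.45 (adjusted p = 0.048), and 2 fell when adjusted over the list alone. Dusp5 did not pass, at -2.37 ± 0.76 (adjusted p = 0.081). Of 47 maternal oocyte transcripts 2 rose and 0 fell (12 and 0 adjusted over the list alone), Oas1d and Rfpl4, the latter from 524 to 1660 CPM (adjusted p = 0.036). Camera placed the list above other genes (adjusted p = 8.7e-07), but not on a spread taken from the list itself (adjusted p = 0.506 with an estimated correlation), and scaling to the list, which sets its own level, brought its median of 0.54 to -0.04. Of 7 Obox genes 2 rose, Obox2 and Obox1, and 0 fell (2 and 0 adjusted over the list alone), while the list's median was -0.84 and its camera direction was up. None of 47 DUX-linked 2-cell genes passed in edgeR (0 rose, 0 fell, and 0 adjusted over the list alone); Tcstv1 was at 1.37 ± 0.44 (adjusted p = 0.078). Ribosomal protein genes (80) and ribosome biogenesis genes (60) were ranked low by camera (adjusted p = 1.3e-10 and 8.2e-08) with 0 members past the threshold in either, also adjusted over the list alone, and with adjusted p = 0.506 for both with an estimated correlation. So were p53 targets (0 rises and 1 fall among 26, also adjusted over the list alone; camera adjusted p = 0.0043) and stress response genes (0 of 22 past the threshold, and 2 falls adjusted over the list alone; camera adjusted p = 0.0096), again with adjusted p = 0.506 with an estimated correlation. The means per embryo of these 4 lists and of the maternal list did not pass exact permutation tests (adjusted p = 0.0892 to 0.16). For the maternal list 4 of 7 SRF-LOF embryos lay above all controls. Below all controls lay 5 of 7 for p53 targets and for stress response genes, 3 for ribosomal proteins and 2 for ribosome biogenesis. Immediate early SRF targets differed by -0.67 in mean log2 CPM (exact permutation p = 0.0376, adjusted p = 0.151), with 5 of 7 embryos below all controls. Actin SRF targets differed by -0.13 (exact permutation p = 0.196, adjusted p = 0.321), with 1 below. SRF-LOF 3 and 8 stood apart on the first principal component described below, at -35.92 and -11.03, with the others at 96.35 to 135.7. The maternal list followed this component across the 35 embryos (r = 0.874).

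The test called 222 genes between SRF-LOF and control, 145 higher and 77 lower, and 0 repeat subfamilies (63 at an unadjusted p under 0.05, and 1 by DESeq2). The gene count was unstable: it was 1 in a fit of these groups alone, 1 with ERCC scaling, 20 (4 higher, 16 lower) with scaling to the maternal list and 881 (360 higher, 521 lower) with DESeq2. Leaving out 1 library gave 8 genes (without SRF-LOF 4) to 1788 (without SRF-LOF 3), and 12, 14 and 1204 without SRF-LOF 7, 6 and 8. Of 22 named genes past the threshold, Srf and Oas1d kept their calls in all 35 such fits. Oas1d lost its call in a fit of these groups alone (adjusted p = 0.141), with the replicate block (adjusted p = 0.122) and with ERCC scaling (adjusted p = 0.0747), where Srf kept it. Dennd6a lost its call without SRF-LOF 4 or 7 (adjusted p up to 0.0803), Akr1b3, Obox2 and Fermt2 without SRF-LOF 4, 6 or 7 (up to 0.0652, 0.0936 and 0.0873), and Hand1 and Osbpl6 without these or control 1 and control 6 respectively (up to 0.0803 and 0.0851). Rfpl4 lost it in 8 fits, Obox1 in 7 and Mcl1 in 29 (up to 0.135, 0.153 and 0.153).

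Many genes that DUX is known to switch on fell with the DUX oligonucleotide. Zscan4f, a 2-cell zinc finger gene (ENSMUSG00000070828.10, chromosome 7, 11397915 to 11402318), fell from 558 ± 695 CPM in controls to 26.9 ± 18.4 in DUX-LOF, -4.37 ± 0.68 on the log2 scale (adjusted p = 2.7e-05, n = 9 each). Its cluster mates Zscan4b, Zscan4e and Zscan4c were at -6.37 ± 1.2, -5.32 ± 1.02 and -3.75 ± 0.74, the translation factor-like 2-cell gene Gm5039 at -5.33 ± 0.78 and Ddit4l, an inhibitor of mTOR signalling, at -4.01 ± 0.50 (adjusted p = 8.4e-07). Mest, an imprinted gene (ENSMUSG00000051855.15, chromosome 6, 30723547 to 30748465), fell from 101 ± 44.9 to 7.29 ± 2.96 CPM (-3.75 ± 0.34, adjusted p = 1.3e-09). Among rises, Klhl40, a muscle gene (ENSMUSG00000074001.3, chromosome 9, 121777607 to 121783818), went from 3 counts over all controls to 249, a ratio of 76.0 (25.7 to 370.9), and Taf7l, a germ cell TAF, from 1 to 379 counts, a ratio of 346.9 (61.9 to 13738.1). Lsmem1 was at least 51.9-fold higher, and Gstm1, a glutathione transferase, and Tnfrsf4, a TNF receptor family member, rose by 5.80 ± 0.95 and 5.38 ± 0.79.

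Of 47 DUX-linked 2-cell genes 28 fell and 2 rose with DUX-LOF (32 and 2 adjusted over the list alone), and the list's summed level went from 10070 ± 6104 CPM in controls to 3180 ± 812. The 2-cell gene B020004J07Rik rose against the list, by 4.20 ± 0.52. Camera gave adjusted p = 4.2e-10 and adjusted p = 0.303 with an estimated correlation. The mean log2 CPM per embryo differed by -1.32 (two-sided exact permutation p = 0.00185, adjusted p = 0.0315). The median of the list was -1.73, and -1.41 and -0.80 with scaling to ERCC and to the maternal list. Of 47 maternal oocyte transcripts 16 fell and 0 rose (17 and 0 adjusted over the list alone; camera adjusted p = 2.9e-05, and adjusted p = 0.408 with an estimated correlation), among them Zp3, a zona pellucida glycoprotein (-2.19 ± 0.41), Rfpl4 (-2.03 ± 0.41), Nlrp4f (-1.87 ± 0.38) and Dppa3, which protects maternal DNA methylation (-1.42 ± 0.27); their median of -0.62 turned to 0.22 with scaling to this list. Their mean differed by -0.55 (exact permutation p = 0.00457, adjusted p = 0.0485).

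Heat shock genes fell in 6 of 18 cases and rose in 0 (6 and 0 adjusted over the list alone) with DUX-LOF, led by the HSP90 cochaperone Ahsa1 (-1.38 ± 0.20) and Hsp90ab1 (-1.18 ± 0.22); camera gave adjusted p = 0.0018, and adjusted p = 0.117 with an estimated correlation. Nuclear oxidative phosphorylation genes fell in 11 of 49 cases and rose in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 7.1e-05, and adjusted p = 0.408 with an estimated correlation), for example Atp5b (-0.88 ± 0.15) and Cox5a (-1.40 ± 0.29), and their median of -0.55 was 0.04 with scaling to the maternal list. The maternal list itself fell here, so scaling to it raises all genes alike. ERCC scaling lay 0.019 from TMM scaling between these groups (log2, interval -0.64 to 0.68). None of 13 mitochondrial mRNAs passed in either direction, nor adjusted over the list alone. Ribosomal proteins had 12 falls and 1 rise among 80 (12 and 1 adjusted over the list alone; camera adjusted p = 2.9e-05, and adjusted p = 0.837 with an estimated correlation). Proteasome genes had 5 falls among 31 (6 adjusted over the list alone; camera adjusted p = 0.0092, and adjusted p = 0.694 with an estimated correlation), at a median of -0.47 that was 0.13 with scaling to the maternal list. The spliceosome list split, with 4 rises and 6 falls among 44 (4 and 6 adjusted over the list alone; median -0.31, and 0.29 with scaling to the maternal list), including Srsf5 (-1.79 ± 0.28) and Snrpg (-1.37 ± 0.30). Ribosome biogenesis had 2 rises and 4 falls among 60 (0 and 3 adjusted over the list alone; median -0.22, and 0.35 with scaling to the maternal list), including Imp4 (-1.57 ± 0.36). The means of the heat shock, oxidative phosphorylation, ribosomal protein and proteasome lists did not pass exact permutation tests (adjusted p = 0.0536, 0.148, 0.23 and 0.455).

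Among 26 p53 targets 7 fell and 1 rose with DUX-LOF (8 and 1 adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.694 with an estimated correlation), at a median of -0.41 that was 0.15 with scaling to the maternal list. Trp53 itself fell by 1.97 ± 0.32 and the BH3-only gene Pmaip1 by 2.83 ± 0.61, while Mdm2, which degrades p53, rose by 0.90 ± 0.23. Cell cycle genes had 3 rises and 6 falls among 39 (3 and 6 adjusted over the list alone), with cyclin Ccne2 at -1.70 ± 0.24, Mki67 at -0.95 ± 0.21, Top2a at 1.23 ± 0.29 and E2f1 at 0.93 ± 0.23. SRF targets of the actin class had 6 rises and 2 falls among 35 (6 and 2 adjusted over the list alone), with Acta1 at 2.93 ± 0.62, Diaph1 at 1.05 ± 0.27, Cfl1 at -1.14 ± 0.22 and Myl6 at -1.28 ± 0.30. Camera did not call this list (adjusted p = 0.416, and adjusted p = 0.694 with an estimated correlation), while its mean differed by 0.32 (exact permutation p = 0.0037, adjusted p = 0.0485). Its summed level went the other way, from 3228 ± 304 CPM in controls to 2821 ± 326 in DUX-LOF. Immediate early targets had 1 rise, Atf3 (2.96 ± 0.73), and 1 fall among 15 (1 and 0 adjusted over the list alone). Preimplantation transcription factors had 2 rises and 1 fall among 22 (2 and 2 adjusted over the list alone), the endoderm factor Gata4 (1.36 ± 0.38) rising and Klf17 (-0.70 ± 0.20) falling, the latter at 0.12 with scaling to the maternal list. Stress response genes had 1 rise and 2 falls among 22, and interferon and RNA sensing genes 1 rise (Mavs, 1.74 ± 0.38) and 2 falls among 15, including Ifitm3 (-1.48 ± 0.37), with the same counts adjusted over the list alone. Obox genes had 0 of 7 past the threshold, also adjusted over the list alone. Of the marker lists, 0 of 4 cumulus and 0 of 2 sperm markers passed, and 1 of 3 blood cell markers rose, the macrophage gene Cd68, from 13.5 to 51.2 CPM (1.93 ± 0.54).

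Internal reads on MERVL-int did not differ with the DUX oligonucleotide by more than the spread (10200 ± 4001 CPM in DUX-LOF, log2 fold change -0.16 ± 0.33, adjusted p = 0.83), nor did MT2_Mm (-0.44 ± 0.35, adjusted p = 0.57). The LTR subtype MT2-Mm_i, chosen after its values were seen, fell by 1.33 ± 0.33 (adjusted p = 0.0122). In 5' reads MT2_Mm fell from 1851 ± 978 to 759 ± 494 CPM (-1.29 ± 0.33, adjusted p = 0.0095), MT2-Mm_i from 10120 ± 8332 to 2053 ± 1024 CPM (-2.30 ± 0.44, adjusted p = 0.000897), and the subtypes ii to v fell as well, by 1.25 to 1.61. Summed over MT2_Mm and its subtypes, 5' reads went from 44970 ± 29750 CPM in controls to 14070 ± 7459 in DUX-LOF (n = 9 each), a difference of -1.57 in mean log2 (exact permutation p = 0.00304, adjusted p = 0.0304 over 10 tests). The same sum in internal reads differed by -0.51 (exact permutation p = 0.123). In SRF-LOF embryos the 5' sum was 44930 ± 17020 CPM (exact permutation p = 0.588 against control).

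Other repeats moved with DUX-LOF in both directions: of 628 tested, 13 rose and 16 fell. This balance depends on the setting, with 3 higher and 1 lower with ERCC scaling, 9 and 2 with the replicate block, and 372 and 3 with scaling to the maternal list. The retroviral IAPLTR1_Mm rose from 89.3 ± 36.6 to 326 ± 74.0 CPM (1.86 ± 0.23, adjusted p = 6.6e-07), IAPEz-int by 1.65 ± 0.26 (adjusted p = 6e-05) and the LINE-1 subfamily L1MDa by 1.2 ± 0.27. X7C_LINE fell by 2.03 ± 0.36 (adjusted p = 0.00041), and MT2B1, an older ERVL LTR, by 1.09 ± 0.25 (adjusted p = 0.0094). IAPLTR2a (-1.52 ± 0.35) and ERVB4_2-I_MM-int (-1.22 ± 0.27) fell in internal reads and stood at 0.40 and 0.41 in 5' reads. By list, IAP and other ERVK had 2 rises among 14, older MaLR and ERVL LTRs 1 fall among 21, and MERVL (2), LINE-1 (6), SINE (8) and satellite (1) entries had 0 calls in internal reads. In 5' reads 65 subfamilies passed, 40 higher and 25 lower.

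**Figure D2:**
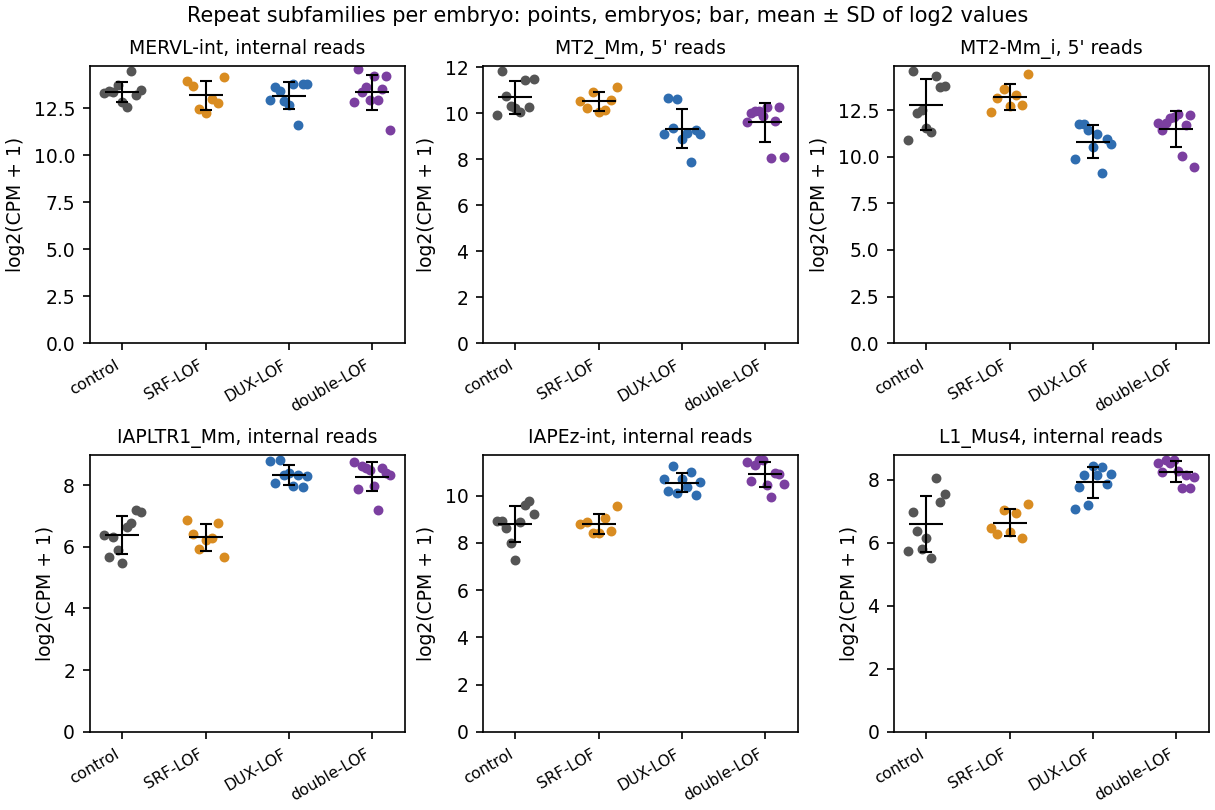
Reads on 6 repeat subfamilies per embryo, by group, on the log2(CPM + 1) scale, internal or 5' as titled, with 1 point per embryo and bars for the mean ± SD. Internal MERVL-int overlaps between all groups, 5' reads on MT2_Mm and MT2-Mm_i are lower in DUX-LOF and double-LOF, and IAP elements are higher there.

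In all, DUX-LOF and control embryos differed in 2055 genes, 1056 higher and 999 lower, of which 891 and 756 changed at least 2-fold. Scaling to ERCC spike-ins gave 845 genes (540 higher, 305 lower), and scaling to the maternal list 3227 (3076 higher, 151 lower). Leaving out any single library gave 1683 to 2235.

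Embryos with both injections differed from controls in 2337 genes, 1155 higher and 1182 lower. Zscan4f fell by 3.62 ± 0.63 (adjusted p = 8.8e-05, n = 10 against 9), Ddit4l by 3.16 ± 0.46 and Mest to a log2 fold change of -3.63 ± 0.33 (adjusted p = 7.2e-10), and Zscan4e went from 305 to 3 counts, 95.6-fold lower (32.4 to 466.0). Ssrp1, a subunit of the FACT histone chaperone (ENSMUSG00000027067.16, chromosome 2, 85037234 to 85047109), fell from 205 ± 72.4 to 14.6 ± 11.8 CPM (-3.74 ± 0.37, adjusted p = 3.3e-09). Klhl40 rose 84.4-fold (28.5 to 412.1), Lsmem1 at least 43.3-fold and Spata20 at least 51.1-fold, and the potassium channel subunit Kcne1 rose by 5.17 ± 0.73. Of 47 DUX-linked 2-cell genes 18 fell and 3 rose (18 and 3 adjusted over the list alone; camera adjusted p = 0.00076, and adjusted p = 0.627 with an estimated correlation), with a mean difference per embryo of -0.76 (exact permutation p = 0.0697) and a median of -1.01 that stood at 0.13 with scaling to the maternal list. Maternal transcripts had 11 falls and 3 rises among 47 (12 and 4 adjusted over the list alone; camera adjusted p = 0.0084, and adjusted p = 0.658 with an estimated correlation), at a median of -0.47 that was 0.37 with scaling to that list, including Dppa3 (-1.94 ± 0.26), the germ cell helicase Ddx4 (-1.91 ± 0.30) and Zp3 (-2.41 ± 0.40).

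Proteasome genes fell in 14 of 31 cases and rose in 0 in double-LOF embryos (17 and 0 adjusted over the list alone; camera adjusted p = 2.9e-07, and adjusted p = 0.295 with an estimated correlation), with Psmd1 at -1.18 ± 0.21 and Psmc2 at -1.50 ± 0.34. Their mean per embryo differed by -0.89 (exact permutation p = 0.00871, adjusted p = 0.0682). Nuclear oxidative phosphorylation genes fell in 20 of 49 cases and rose in 0 (22 and 0 adjusted over the list alone; camera adjusted p = 7.1e-08, and adjusted p = 0.243 with an estimated correlation), with Ndufa4 at -1.83 ± 0.34. Their mean per embryo was at -0.86 against control (exact permutation p = 0.000693, adjusted p = 0.0196, 7 of 10 embryos below all controls). Heat shock genes fell in 8 of 18 cases (9 adjusted over the list alone; camera adjusted p = 0.00087, and adjusted p = 0.0936 with an estimated correlation), with Hsp90ab1 at -1.34 ± 0.21 and a mean difference of -0.63 (exact permutation p = 0.000963, adjusted p = 0.0205). Ribosomal proteins fell in 24 of 80 cases and rose in 1 (37 and 1 adjusted over the list alone; camera adjusted p = 5.7e-12, and adjusted p = 0.617 with an estimated correlation), with Rpl15 at -1.68 ± 0.29. Their mean differed by -0.95 (exact permutation p = 0.0135, adjusted p = 0.0843). Ribosome biogenesis genes fell in 15 of 60 cases (17 adjusted over the list alone; camera adjusted p = 0.00019, and adjusted p = 0.752 with an estimated correlation), with Ebna1bp2 at -2.59 ± 0.61. Their mean differed by -0.67 (exact permutation p = 0.117, adjusted p = 0.236). Spliceosome genes fell in 11 of 44 cases and rose in 2 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0089, and adjusted p = 0.676 with an estimated correlation). Their mean differed by -0.43 (exact permutation p = 0.0768, adjusted p = 0.172). With scaling to the maternal list the medians of these lists came to between -0.10 (proteasome, -0.95 otherwise) and 0.37 (ribosome biogenesis, -0.61 otherwise).

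Among p53 targets 10 of 26 fell and 1 rose in double-LOF embryos (10 and 1 adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.612 with an estimated correlation), with Trp53 at -2.55 ± 0.32, Plk2 at -2.38 ± 0.50 and Mdm2 at 1.05 ± 0.22. SRF targets had 5 rises and 4 falls among 35 actin genes and 1 rise and 2 falls among 15 immediate early genes (5, 4, 2 and 2 adjusted over the list alone), with Acta1 at 2.92 ± 0.61, Cfl1 at -1.31 ± 0.22 and Dusp5 at -3.27 ± 0.72. The rise was Atf3 (2.25 ± 0.72), which had adjusted p = 0.0656 without double-LOF 1. Cell cycle genes had 3 rises and 6 falls among 39 (3 and 6 adjusted over the list alone), with the spindle checkpoint kinase Bub1b at 1.71 ± 0.32 and Cdc20 at -1.91 ± 0.45.

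MERVL-int was at 12360 ± 6746 CPM in double-LOF embryos (0.11 ± 0.32, adjusted p = 0.85) and MT2_Mm at -0.20 ± 0.34 (adjusted p = 0.74). With scaling to the maternal list these were 1.22 (adjusted p = 0.0107) and 1.07 (adjusted p = 0.0353). In 5' reads MT2_Mm fell by 1.08 ± 0.32 (adjusted p = 0.0199) and MT2-Mm_i by 1.59 ± 0.42 (adjusted p = 0.00794), while the 5' sum over the LTR and its subtypes, 23320 ± 10600 CPM, differed from control by -0.86 (exact permutation p = 0.0761). Of 628 repeat subfamilies 43 rose and 8 fell, against 18 higher and 0 lower with ERCC scaling and 490 and 0 with scaling to the maternal list. IAPEz-int rose by 2.03 ± 0.26 and IAPLTR1_Mm by 1.85 ± 0.23 (adjusted p = 5.7e-07 for both), L1_Mus4 from 115 ± 74.6 to 313 ± 68.8 CPM (1.44 ± 0.27, adjusted p = 0.00088) and MusHAL1 by 1.68 ± 0.32. MLTR31D_MM fell by 1.78 ± 0.45. The count of 51 was 32, 22, 20, 19 and 29 without control 1, 3, 4, 5 and 6, 28 and 22 without double-LOF 1 and 5, and 88 (72 higher, 16 lower) in 5' reads. For genes, leaving out 1 library gave 1954 to 2570, ERCC scaling 1250 (739 higher, 511 lower), no count filter 3047 (1928 higher, 1119 lower) and scaling to the maternal list 4071 (3947 higher, 124 lower).

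**Figure D3:**
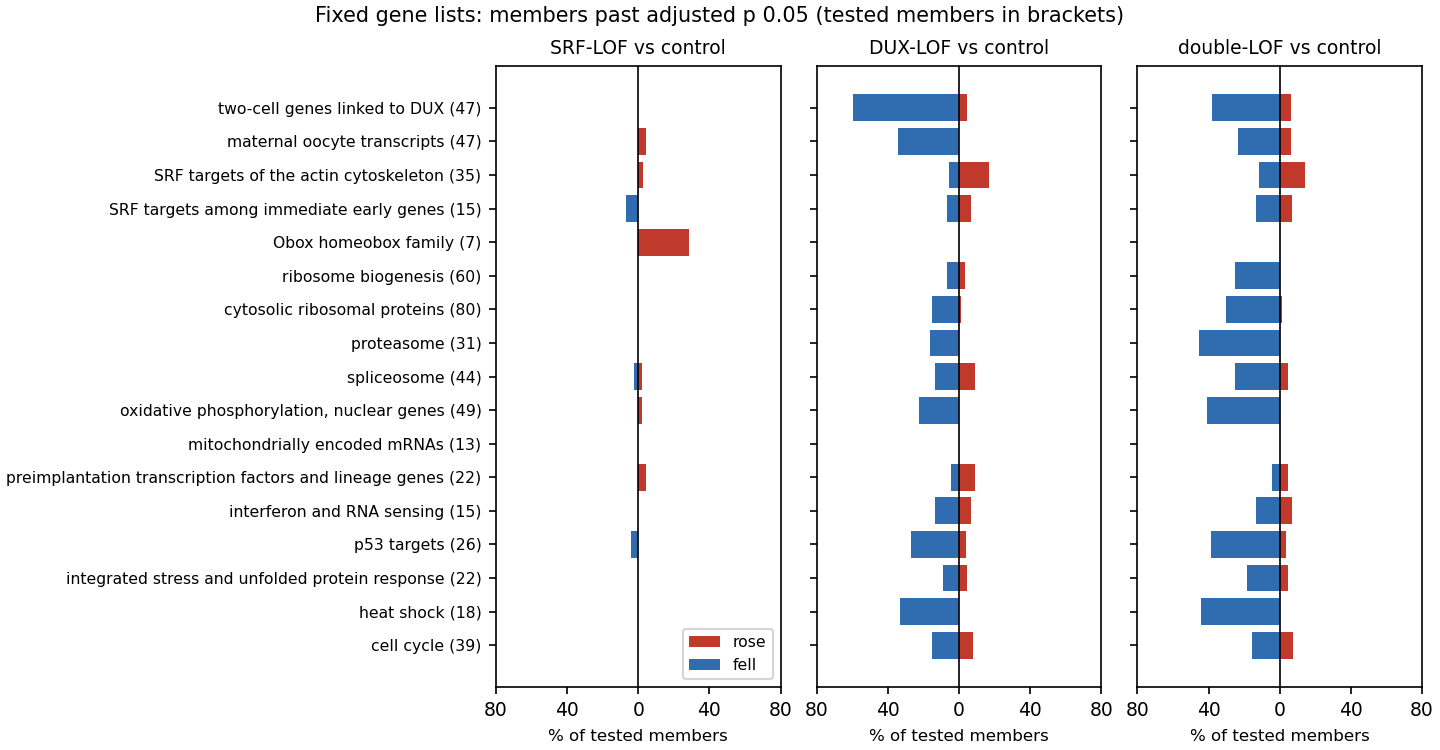
Percent of tested members of each fixed gene list, cell marker lists aside, that passed adjusted p 0.05, higher or lower, in the comparisons of each LOF group with control, with the number of tested members in brackets. DUX-linked 2-cell genes have the most falls in DUX-LOF, 28 of 47, and oxidative phosphorylation and proteasome genes fall in 20 of 49 and 14 of 31 cases in double-LOF.

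Adding SRF mRNA to the DUX oligonucleotide moved little past the threshold. Between double-LOF and DUX-LOF embryos 1 gene passed, Srf (4.80 ± 0.42, adjusted p = 1.4e-09; n = 10 against 9), with 745 genes at an unadjusted p under 0.05, and DESeq2 also called 1. The 2-cell genes AF067061 (2.39 ± 0.73), BB287469 (2.12 ± 0.69) and Gm8300 (1.70 ± 0.53) did not pass (adjusted p = 0.67 each). Of 47 DUX-linked 2-cell genes 0 passed over all genes and 9 were higher adjusted over the list alone. Camera placed the list up (adjusted p = 2.9e-09, and adjusted p = 0.479 with an estimated correlation) and its mean per embryo differed by 0.56 (exact permutation p = 0.0519). The maternal list had 0 calls, also adjusted over the list alone (camera adjusted p = 0.0051, and adjusted p = 0.479 with an estimated correlation). Camera placed 6 lists down, each with 0 calls, also adjusted over the list alone: ribosome biogenesis (adjusted p = 3.7e-09), ribosomal proteins (adjusted p = 5e-07), proteasome (adjusted p = 2.1e-06), spliceosome (adjusted p = 0.0041), oxidative phosphorylation (adjusted p = 0.005) and stress response (adjusted p = 0.0394). With an estimated correlation these had adjusted p = 0.506 for ribosomal proteins and adjusted p = 0.479 for the others. With scaling to the maternal list the medians for ribosome biogenesis and ribosomal proteins turned from -0.43 and -0.31 to 0.006 and 0.02. The interferon and RNA sensing list had 0 of 15 past the threshold, also adjusted over the list alone, and camera did not call it (adjusted p = 0.0538, and adjusted p = 0.479 with an estimated correlation). Its mean differed by -0.53 (exact permutation p = 0.00454, adjusted p = 0.0485, 5 of 10 embryos below all DUX-LOF). Of repeats, X7C_LINE rose by 2.15 ± 0.36 (adjusted p = 0.00039) and no other passed. The gene count was 2 without any 1 of SRF-LOF 3, 5, 6, 8 and 9, and the repeat count was 10 without double-LOF 10 and 0 in 5' reads.

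Double-LOF embryos differed in many genes from SRF-LOF embryos, which received no oligonucleotide. This comparison thus carries any effect of an oligonucleotide as such beside that of the one against DUX. Between double-LOF and SRF-LOF embryos 3315 genes differed, 1721 higher and 1594 lower. Of the genes named above for SRF-LOF, whose choice by a rise in the same embryos favours a fall here, Rfpl4 was at -3.49 ± 0.43 (adjusted p = 3.2e-07), Oas1d at -2.22 ± 0.39 and Obox2 at -2.34 ± 0.41, and Obox1 at -1.48 ± 0.39, with adjusted p = 0.0513 without SRF-LOF 6. Ssrp1 fell by 4.33 ± 0.38, Mest by 3.98 ± 0.34 and Zscan4e from 475 to 3 counts, 203.6-fold (69.2 to 990.6). Cyp2c65 was at least 50.3-fold higher and the growth factor gene Gdf5 154.8-fold (27.5 to 6143.9). Maternal transcripts fell in 27 of 47 cases and rose in 1 (28 and 2 adjusted over the list alone; camera adjusted p = 1.1e-08, and adjusted p = 0.236 with an estimated correlation), with a mean difference of -0.99 (exact permutation p = 0.000103, adjusted p = 0.00437). The 2-cell list had 21 falls and 1 rise among 47 (23 and 1 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.594 with an estimated correlation), with a mean difference of -1.21 (exact permutation p = 5.14e-05, adjusted p = 0.00437, 10 of 10 double-LOF embryos below all 7 SRF-LOF embryos). Both medians, -0.94 and -1.11, turned to 0.26 with scaling to the maternal list. Proteasome genes fell in 10 of 31 cases (10 adjusted over the list alone; camera adjusted p = 0.00897, and adjusted p = 0.831 with an estimated correlation), and oxidative phosphorylation genes in 13 of 49 (13 adjusted over the list alone; camera adjusted p = 0.00897, and adjusted p = 0.831 with an estimated correlation). Heat shock genes fell in 5 of 18 (5 adjusted over the list alone; camera adjusted p = 0.0176, and adjusted p = 0.236 with an estimated correlation), and 0 members of these 3 lists rose. Their medians of -0.67, -0.44 and -0.45 turned to 0.93, 0.90 and 0.83 with scaling to the maternal list, and their means per embryo did not pass (exact permutation p = 0.174, 0.093 and 0.129, adjusted p = 0.295, 0.203 and 0.241). SRF targets of the actin class had 8 rises and 3 falls among 35 (12 and 5 adjusted over the list alone; camera adjusted p = 0.681), Fermt2 being at -1.33 ± 0.26, and Gata4 rose by 2.32 ± 0.43 and Klf17 fell by 1.19 ± 0.20. Fermt2 and Klf17 turned in direction with scaling to the maternal list. Among marker lists Odf2 (sperm, 0.64 ± 0.23) and Lyz2 (blood, 2.45 ± 0.93) rose.

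Of repeats, 63 rose and 5 fell in double-LOF against SRF-LOF, among them IAPEz-int (2.13 ± 0.29) and L1_Mus4 (1.61 ± 0.30). The count of 68 was 36, 44 and 44 without SRF-LOF 4, 5 and 6, 43 and 104 without double-LOF 1 and 7, and 144 (111 higher, 33 lower) in 5' reads. It was 172 (171 higher, 1 lower) with ERCC scaling, 620 (620 higher, 0 lower) with scaling to the maternal list and 31 (28 higher, 3 lower) with the replicate block. MERVL-int was at 0.23 ± 0.34 and MT2_Mm at -0.13 ± 0.36, neither past the threshold, and the 5' sum over the LTR and its subtypes at -1.09 (exact permutation p = 0.00648, adjusted p = 0.0324, 8 of 10 embryos below all SRF-LOF). ERCC scaling gave 2349 genes (1900 higher, 449 lower) and scaling to the maternal list 7184 (7059 higher, 125 lower), where MERVL-int was at 1.71. Srf itself was higher in double-LOF than in SRF-LOF by 1.03 ± 0.39 (adjusted p = 0.043), a call lost in 11 of 35 fits that leave out 1 library (adjusted p up to 0.088).

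The interaction asks whether SRF mRNA acts differently with and without the DUX oligonucleotide only if an oligonucleotide as such has no effect. Controls received a scrambled one and SRF-LOF embryos none, so the contrast also carries that effect. It gave 0 genes and 0 repeats in edgeR. At an unadjusted p under 0.05 there were 831 genes and 28 repeats, and DESeq2 called 0 and 3. Oas1d, at -2.11 ± 0.53, and Fermt2, at -1.32 ± 0.37, had adjusted p = 0.52. MERVL-int was at 0.40 and MT2_Mm at 0.31, within the spread. The maternal list had 0 calls (0 rises and 1 fall adjusted over the list alone; camera direction down, adjusted p = 0.00081, and adjusted p = 0.986 with an estimated correlation), and its median of -0.23 turned to 0.15 with scaling to this list and to 0.04 with ERCC scaling. Camera placed ribosomal proteins up with the same 2 values and 0 calls, also adjusted over the list alone. Leaving out 1 library gave 0 genes in each of 35 fits and up to 4 repeats (without SRF-LOF 3).

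The comparisons with control share the control embryos, so their fold changes were compared with unchanged groups simulated against the same controls and with split controls. Across genes, DUX-LOF and double-LOF fold changes correlated at r = 0.866 with a covariance of 0.907, against 0.509 and 0.120 in 20 simulations and 0.615 and 0.766 with the controls split. Of the calls, 797 genes were higher and 653 lower in both, where independent lists would share 102.2 and 98.9, and 0 went opposite ways. SRF-LOF and DUX-LOF fold changes correlated at -0.060 with a covariance of -0.054, below the 0.465 and 0.120 of the simulations, and at -0.106 with split controls. They shared 11 rises and 8 falls (independent 12.8 and 6.44), and 22 genes went opposite ways. With split controls they shared means of 1.7 and 0.9 (independent 8.34 and 7.17), and 45.7 went opposite ways. SRF-LOF and double-LOF correlated at 0.179 with a covariance of 0.161 (simulated 0.471 and 0.119, split 0.067 and 0.047), with 18 rises and 18 falls in common (independent 14.03 and 7.62) and 10 opposite. With split controls these were 3.2 and 4 (independent 7.1 and 5.505) and 24.55. The shared controls favour calls in common, and 2 parts of 1 set of controls, which lie on opposite sides of its mean, favour opposite calls, so neither count alone measures sharing. Genes are not independent replicates in these correlations. The simulations drew each gene independently and leave out variation that genes share, so they do not show how far these values vary by chance.

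**Figure D4:**
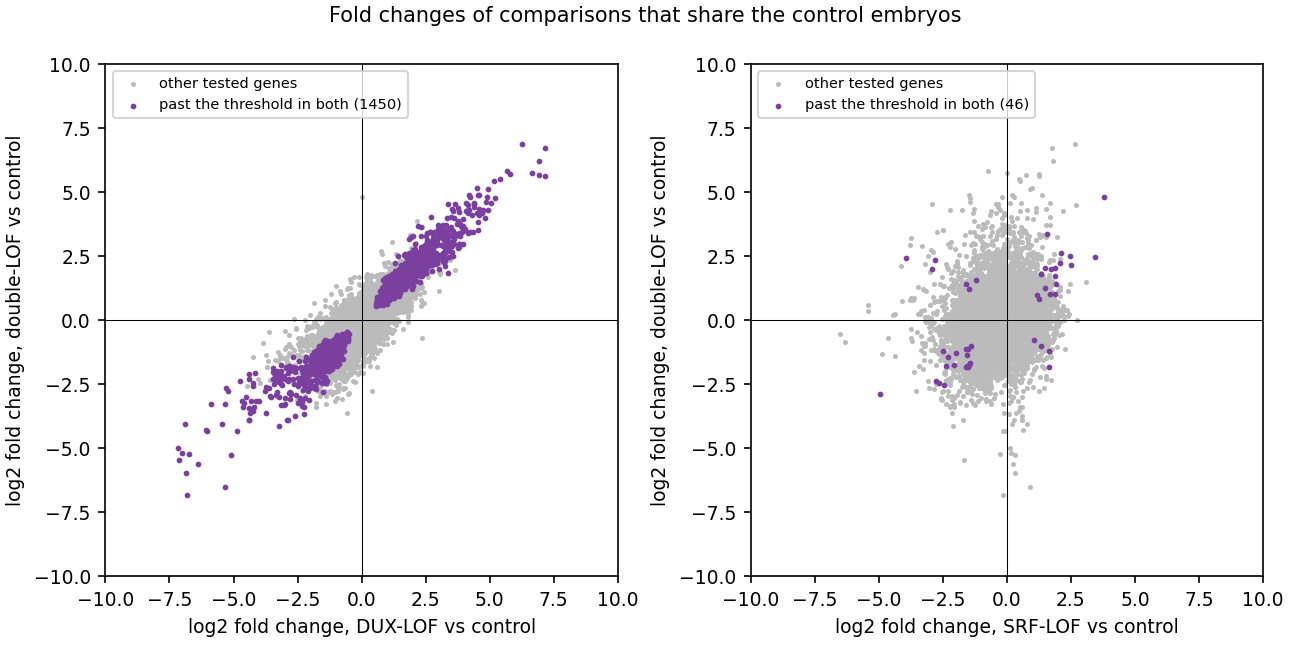
Log2 fold changes of tested genes in double-LOF against control, plotted against those in DUX-LOF and in SRF-LOF, with 1 point per gene and genes past the threshold in both comparisons coloured. In the DUX-LOF panel 1450 genes pass in both, and in the SRF-LOF panel 46 do.

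Embryos of a group also differed among themselves. The first principal component of log2 CPM held 34.7% of the variance and the second 14.1%. Control (-81.04 to 101.77), SRF-LOF (-35.92 to 135.7) and double-LOF embryos (-107.51 to 96.22) were spread along the first, and DUX-LOF embryos less so (-82.99 to -13.3). Across the 35 embryos the score on it correlated with the mean level of maternal transcripts (r = 0.874, rho = 0.820). It correlated more strongly, the other way, with preimplantation transcription factors (r = -0.954), stress response genes (r = -0.926) and ribosome biogenesis (r = -0.887).

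**Figure D5:**
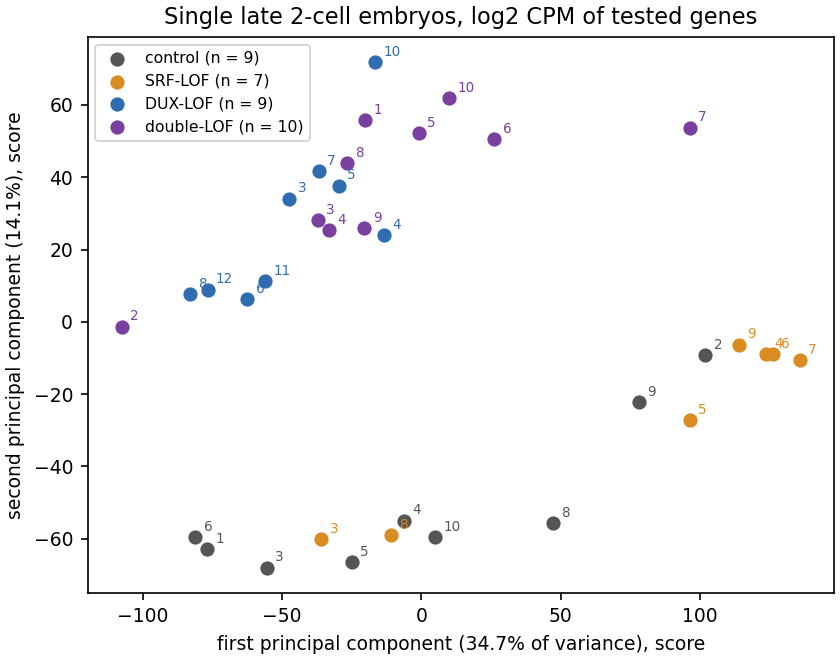
Embryos on the first (34.7% of variance) and second (14.1%) principal components of log2 CPM of internal gene counts, with 1 numbered point per embryo, coloured by group. DUX-LOF and double-LOF embryos overlap, and control, SRF-LOF and double-LOF embryos spread along the first component.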

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

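The tests of single embryos and those of permuted groupings were planned, as were the receptor genes, the control axis and the MTA_Mm test. The tests of depth, ERCC scaling, counts per ERCC count, the control axis over splits of the controls, the other LTRs and MERVL-int in 5' reads, and the 5' to internal ratio were chosen after the results were seen. A single embryo far from the rest of its group was looked for in 56 groups of values, and 6 were marked. About 1 in 20 would be marked by chance if values were normal, which counts and CPM need not be. Some measures also vary together, so the 6 do not show an excess. Control 6 had 2039475 gene counts, the next control 1454404. Control 8 stood highest among controls for MERVL-int (22730 CPM, next 13550) and MT2_Mm (728.6 CPM, next 410.2). Double-LOF 2 stood lowest for maternal oocyte transcripts, at a mean log2 CPM of 6.069 with the next at 6.968. The library labelled DUX-LOF 10 stood highest in its group for Duxf3 (117.2 CPM, next 8.123) and for Srf (51.22 CPM, next 31.23). In other genes it lay outside the control range, as its group did. Zscan4f was at 7.76 CPM (lowest control 33.42), Ddit4l at 31.04 (lowest control 105.1) and Klhl40 at 7.76 (highest control 1.47). These genes were chosen with this embryo in its group.

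Embryos were regrouped at random, with 100 groupings per comparison counting the real one. The real number of genes or more was reached in 4 groupings for SRF-LOF against control (222 genes, highest other 4490), 1 for DUX-LOF (2055, 94), 1 for double-LOF (2337, 411), 2 for double-LOF against DUX-LOF (1, 1), 1 for double-LOF against SRF-LOF (3315, 2552) and 100 for the interaction (0, 8). For repeats it was reached in 100 groupings for SRF-LOF (0, 30), 1 for DUX-LOF (29, 2), 2 for double-LOF (51, 255), 4 for double-LOF against DUX-LOF (1, 9), 1 for double-LOF against SRF-LOF (68, 18) and 100 for the interaction (0, 8).

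Genes higher in DUX-LOF than in control embryos could come from genomic DNA, from unspliced RNA, from depth or from the scaling. Counts on 1731 olfactory and vomeronasal receptor genes, which embryos should not express, took 0.949 of their control share (bootstrap interval 0.71 to 1.32), which argues against genomic DNA, while unspliced RNA was not tested and stays open. Mean gene totals differed by a ratio of 1.1, with no interval taken, which argues against a difference in mean depth. The depth of single embryos was not tested here. ERCC scaling lay 0.019 from TMM scaling between these groups (log2, interval -0.64 to 0.68), short of the median of 1.70 by which the 1056 genes were higher, which argues against the scaling as the whole cause, if each embryo received the same spike-in amount, for the 1044 genes higher by more than 0.64. A response to the loss of DUX is a hypothesis, found and tested on the same embryos.

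Control and SRF-LOF embryos spread along the first principal component, as did double-LOF embryos, with the widest range (-107.51 to 96.22). The SRF-LOF fold changes correlated at r = 0.675 across genes with the main axis among controls alone (0.6075 to 0.6805 leaving out each control), and double-LOF against DUX-LOF at 0.519, without controls. With the axis from 5 controls and the fold change against the other 4, the median absolute r over 126 splits was 0.654 (quartiles 0.523 and 0.712, lowest 0.0101), against 0.219 for DUX-LOF and 0.188 for double-LOF, so that a difference also present between controls may account for part of the SRF-LOF differences, and whether it is developmental progress was not tested. SRF-LOF 3 and 8, lowest of their group on the first component (-35.92 and -11.03), also had its lowest Srf reads, 181 and 97.0 CPM. SRF-LOF 6, at 215 CPM, stood at 125.94. Double-LOF 2, lowest of its group (-107.51), had its lowest Srf reads (217 CPM), while double-LOF 5, with the highest (1658 CPM), stood at -0.83. Whether the amount of injected mRNA plays a part was not tested, and controls, which spread as well, received none. Counts per ERCC count (rho = -0.273, p = 0.112) and gene counts (rho = -0.341, p = 0.0459, adjusted p = 0.23 over 15 relations) leave RNA content and depth open, as the trends are weak over 35 embryos. Among the 9 controls alone gene counts went with the axis at rho = -0.817 (exact p = 0.0108, adjusted p = 0.162).

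5' reads on MT2_Mm were lower in DUX-LOF (-1.29, adjusted p = 0.0095) while internal reads on MERVL-int did not pass. The log2 ratio of the first to the second was -3.85 ± 0.80 in DUX-LOF and -2.70 ± 0.61 in control embryos (exact permutation p = 0.00424, adjusted p = 0.00707, 7 of 9 below all controls), but the ratio was built from this pattern. It was also lower in double-LOF than in SRF-LOF embryos, which are other embryos than these, by 1.09 (exact permutation p = 0.00365, adjusted p = 0.00707, 6 of 10 below all SRF-LOF), which argues against a chance difference between the read classes. In that comparison 5' reads on MT2_Mm alone did not pass the threshold. Mean internal MERVL-int, the other part of the ratio, was 12360 CPM in double-LOF and 10510 in SRF-LOF embryos. Lower capture of all 5' ends could not be tested with these values. They are scaled to the 5' gene rows, so an equal loss at all 5' ends would cancel in each of them. 5' reads on MERVL-int were at 0.0158 (interval -0.64 to 0.67). The 420 other LTR subfamilies were at a median of 0.00175 (quartiles -0.406 and 0.376), with 12 of them as low as MT2_Mm. The fall was thus not shared by most other LTR subfamilies. The planned test required MTA_Mm to lie clearly above MT2_Mm, and this was not met. MTA_Mm was at -0.684, and its interval of -1.40 to 0.03 includes the MT2_Mm value of -1.29. Less initiation at MT2 LTRs without DUX is a hypothesis that these reads do not settle.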

How the results depend on the processing

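ERCC scaling, leaving out each library and leaving out 3 doubted libraries (DUX-LOF 10, double-LOF 6 and double-LOF 7) were chosen after seeing the data. Of 211 named values 173 passed the threshold. Over all alternatives other than single left-out libraries, named values kept direction and side of the threshold in 2004 cases, lost the threshold in 217, gained it in 26 and reversed in 24. MERVL values were judged in the same way. A count was held to be the same if it stayed within a fixed ratio of the main count, and moved otherwise. Counts and MERVL values together were the same in 207 cases, with 44 counts moved, and 12 MERVL values reversed and 4 past the threshold anew. The median log2 fold change of all genes moved from -0.10 to -0.46 (SRF-LOF) and from 0.03 to 0.42 (double-LOF against SRF-LOF) with ERCC scaling. With scaling to the maternal list it moved to -0.62 (SRF-LOF), 0.66 (DUX-LOF), 0.77 (double-LOF), 0.11 (double-LOF against DUX-LOF), 1.40 (double-LOF against SRF-LOF) and 0.75 (interaction). Causes below were not tested, except that scaling moves all genes alike.

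The 222 SRF-LOF genes became 881 with DESeq2, 115 without a filter, 20 with maternal scaling, 1 with only the groups compared, 3 with the replicate block, 1 with ERCC scaling and 364 without the doubted libraries. DUX-LOF genes became 3227 with maternal and 845 with ERCC scaling, double-LOF genes 4071 and 1250, and double-LOF against SRF-LOF 7184 with maternal scaling. Double-LOF against DUX-LOF gave 2 genes without a filter, with maternal scaling and in 5' reads, and 0 repeats in 5' reads. SRF-LOF repeats were 1 with DESeq2 and 1 in 5' reads. DUX-LOF repeats were 53 with DESeq2, 375 with maternal scaling, 11 with the block, 65 in 5' reads and 4 with ERCC scaling. Double-LOF repeats were 91 with DESeq2, 21 without a filter, 490 with maternal scaling, 22 with only the groups compared, 88 in 5' reads and 18 with ERCC scaling. Against SRF-LOF they were 122 with DESeq2 size factors, 160 with DESeq2, 36 without a filter, 620 with maternal scaling, 31 with the block, 144 in 5' reads, 172 with ERCC scaling and 112 without the doubted libraries. Interaction repeats were 2 with DESeq2 size factors, 3 with DESeq2, 2 without a filter, 3 with maternal scaling, 1 with the block and 2 without the library under 0.25 of the median total. Of 36 list calls 0 held with an estimated correlation.

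In 5' reads MERVL-int was at 0.0466 (SRF-LOF) and 0.0158 (DUX-LOF), MT2_Mm at -1.29 (DUX-LOF) and -1.08 (double-LOF), MT2-Mm_i at 0.041 (SRF-LOF), Duxf3 at -0.392 (DUX-LOF) and -0.857 (double-LOF), IAPLTR2a at 0.395 and ERVB4_2-I_MM-int at 0.409 (DUX-LOF), and MTE-int at 0.45 (double-LOF). With the replicate block MT2_Mm was at 0.055 (SRF-LOF), Srf at -0.0784 and Duxf3 at -1.09 (DUX-LOF), MERVL-int at -0.0053 and Duxf3 at -0.0308 (double-LOF), and Duxf3 at 1.06 (double-LOF against DUX-LOF) and 0.145 (interaction). With ERCC scaling MERVL-int was at 0.00406 (DUX-LOF) and MT2_Mm at 0.227 (double-LOF against SRF-LOF). With maternal scaling MERVL-int was at 0.613 (DUX-LOF), 1.22 (double-LOF) and 1.71 (double-LOF against SRF-LOF), and MT2_Mm at 0.40, 1.07 and 1.40. Klf17 was then at 0.125 (DUX-LOF), Atp5b at 0.0941, MTE-int at 0.0222 and MT2-Mm_i at 0.103 (double-LOF), and against SRF-LOF Duxf3 was at 0.755, Klf17 at 0.211, Fermt2 at 0.103, Hsp90ab1 at 0.135 and MT2-Mm_i at 0.489. Without the doubted libraries Srf was at -0.175 and Duxf3 at -1.24 (DUX-LOF), MT2_Mm at 0.0118 (double-LOF) and 0.0481 (double-LOF against SRF-LOF), and Duxf3 at 1.60 (double-LOF against DUX-LOF) and 0.704 (interaction).

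Leaving out each library gave ranges of 8 to 1788 genes for SRF-LOF, 1683 to 2235 for DUX-LOF, 1954 to 2570 for double-LOF, 1 to 2 for double-LOF against DUX-LOF, 2629 to 4014 for double-LOF against SRF-LOF and 0 to 0 for the interaction. For repeats they were 0 to 1, 25 to 37, 19 to 75, 1 to 10, 36 to 104 and 0 to 4. MERVL-int ranged from -0.288 to 0.0541 (SRF-LOF), -0.234 to 0.0403 (DUX-LOF), -0.037 to 0.317 (double-LOF), 0.111 to 0.398 (double-LOF against DUX-LOF), 0.0975 to 0.433 (double-LOF against SRF-LOF) and 0.223 to 0.578 (interaction). MT2_Mm ranged from -0.279 to 0.155, -0.551 to -0.196, -0.417 to 0.0367, 0.0076 to 0.359, -0.344 to 0.0787 and 0.0775 to 0.519 in the same order. Internal MT2-Mm_i kept its fall in DUX-LOF in all 35 fits and lost it in double-LOF in 17, with adjusted p up to 0.099. MT2_Mm summed with its subtypes, also added after seeing the data, was at -0.138, -0.53, -0.293, 0.237, -0.155 and 0.375. Small changes can be missed: of 100 simulated genes changed 2-fold, 13 to 17 were found per pair of groups and 3 for the interaction. The simulated genes were drawn independently of each other, unlike those of the real embryos.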

Other observations

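The enrichment of gene families by name or type was tested after the results were seen, over 1512 combinations with a one-sided Fisher's exact test. The test treats genes as independent, while members of a family can vary together and near-identical copies share reads, so its p-values can be too small. Over all tested genes 8.37% were lower in DUX-LOF, 9.9% lower in double-LOF and 1.21% higher in SRF-LOF. In DUX-LOF, 181 of 1155 genes with the provisional stem Gm were lower than in control (adjusted p = 7.3e-15), as were 29 of 90 unprocessed pseudogenes (adjusted p = 6.59e-08), 9 of 16 Zscan genes (adjusted p = 0.000279) and 14 of 54 Eif genes, which include translation initiation factors (adjusted p = 0.0128). With scaling to the maternal list the lower calls of this comparison went from 999 to 151 and the median of all genes from -0.08 to 0.66. In double-LOF embryos 20 of 54 Eif genes (adjusted p = 4.12e-05), 10 of 18 Cox genes (adjusted p = 0.000342) and 11 of 27 Polr genes (adjusted p = 0.00377) were lower, in a comparison where scaling to the maternal list moved the median of all genes from -0.08 to 0.77. In SRF-LOF 4 of 22 Fbxw genes were higher (adjusted p = 0.015), which rests on 222 calls that became 1 in a fit of the compared groups alone and 8 to 1788 without 1 library.

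Embryos with the same number in different groups were compared as possible litter mates, a grouping the labels do not give. Over 41 such pairs the correlation of deviations from the group means had a median of 0.031 (-0.568 to 0.551), against 0.001 for different numbers. It was over 0.1 in 16 pairs. Of 82 best matches 13 shared a number, with no chance rate taken. Embryos were not paired in the main test, and a weak pairing is not excluded. The replicate block given above, which groups embryos by number, left fewer SRF-LOF genes past the threshold.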
